A study of Bos taurus with 16 samples.

How the data were processed

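RNA was measured on Affymetrix bovine genome arrays in 16 samples, 11 of endometrium taken with a cytobrush and 5 of blastocysts. Per the labels, the series drew on 49 superovulated cows, brushed 2 h before insemination (day 0) and again before the uterus was flushed (day 7). Cows counted as healthy (HE) when the brush held 0 polymorphonuclear cells and as having subclinical endometritis (SE) when it held more. Each array carried RNA from a pool, and a blastocyst pool held 10 embryos. The protocol speaks of 3 pools per group, of which 2 were deposited for day 7 HE endometrium and 2 for HE blastocysts; the latter are called replicates 1 and 2 here and carry the pool numbers 2 and 3 in their titles. The RNA was amplified in 2 rounds from 15 ng and labelled with biotin.

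The deposited values are GCRMA signals on the log2 scale, made by the authors from the scanned arrays with background correction, quantile normalization and a summary per probe set. The processing notes name GCRMA and limma with no version, role or order. The raw scans were not used here. The blastocyst columns share an exact lowest value, 2.20, and a distribution of their own; whether the tissues were normalized apart is not given in the sources used here. No level was compared between endometrium and blastocysts.

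The table held 24128 probe sets. The 112 control probe sets were left out of all tests and used only to compare arrays. Gene names came from the annotation supplied for this platform: 13292 probe sets carried exactly 1 symbol, for 9155 genes, 86 carried several and 10638 had no gene named here. The gene numbers of 13263 probe sets were found in a RefSeq gene table, and 0 symbols needed an update. A genome was not used here, so no coordinates are given.

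Values were analysed in R 4.3.3 with limma 3.58.1; tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. A probe set was kept when its log2 value was above 4 on at least 2 arrays of the tissue, which kept 13421 in endometrium and 11014 in blastocysts. limma's moderated test (linear fit to group means, empirical Bayes without an intensity trend) was run on all 11 endometrium arrays in 1 fit and on the 5 blastocyst arrays in another. Tests were two-sided. P-values were adjusted by Benjamini and Hochberg over all kept probe sets of a contrast, with a threshold of 0.05. The contrasts were SE over HE on day 0, SE over HE on day 7, day 7 over day 0 within HE and within SE, the interaction of status and day, and SE over HE in blastocysts. Changes are log2 differences of group means with limma's standard error, and levels are means with the SD between arrays. The number of arrays limits the precision of every value.

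Gene lists were fixed beforehand, 36 in all, covering cell types, inflammation, hormone response, stress, metabolism and embryo lineages. A list was tested when at least 5 of its members were measured, each by the kept probe set with the highest mean. Tests used camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Each was repeated with the correlation estimated from the data and with fry, which asks whether the members move one way on balance without comparing them with other genes. Among 160 list tests, 26 had a median or mean opposite in sign to the test, 0 of these past the threshold. Too few members were measured in endometrium for erythrocyte markers (GYPC alone), endothelial markers (CLDN5 alone) and smooth muscle markers (ACTA2, TAGLN and MYLK). In blastocysts 0 neutrophil, 0 macrophage and 0 erythrocyte markers were kept. Lymphocyte markers (GZMB, LCK and ZAP70), endothelial markers (PECAM1 and TEK) and the sex-linked list (XIST and EIF1AX) were too few to test. Correlations of log2 changes between contrasts were computed across probe sets, which are not independent replicates, so no p is given. There were 3 of these, and none shared an array between its sides.

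The genes named follow a rule. In each contrast they are the 10 with the largest rise and the 10 with the largest fall among probe sets past the threshold with exactly 1 symbol. Where fewer than 5 passed in a direction, the genes of smallest p filled up to 5 and are given as values. The rule also named members of reported lists with the largest test statistics, at most 2 per direction, and genes chosen in advance. Of these, PGR, ESR1, CDX2, NANOG and GATA3 were not kept or not named on the array. Probe set Bt.15970.1.A1_at, which has no symbol, falls outside the rule and was chosen after its values were seen. In SE over HE on day 7, 1 gene that the rule names is not reported here. The design, the lists and the rule were set before the data were examined. The naming of list members was narrowed after values had been seen: in the status contrasts to members moving with a called list, in the day contrasts to members past the threshold, and to none for the interaction.

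Alternatives changed 1 choice at a time: no filter, a filter at log2 above 5, median centring, a further quantile normalization, an intensity trend or robust estimate in the empirical Bayes step, array weights, gene means over probe sets, the replicate number as a block, only the compared groups in the fit, all 16 arrays in 1 fit for blastocysts, an adjusted p under 0.10, and each array left out in turn. Robust estimates cannot be passed to camera, so the lists have no such alternative. Alternatives chosen after seeing the data left out day 0 SE replicate 2 and day 7 HE replicate 1 together, and added the spike control level as a covariate for blastocysts.

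The procedure was tested on simulated data with the same group sizes and independent noise for each probe set. Of probe sets made to change by 1 log2 unit, it recovered 59% in the day 0 status contrast (13204 tested), 50.5% on day 7 (13211), 51.5% for the day change in HE (13194), 59.2% in SE (13233), 17.2% for the interaction (13224) and 9% in blastocysts (11052). At 2 log2 units it recovered 92.9%, 92.9%, 93.9%, 95.9%, 75.8% and 63.3%. With no change simulated it called 0 probe sets in each contrast except 1 for the day change in HE. It called 0 lists except 2 for the interaction. List members were uncorrelated in the simulation, unlike in the data, where the estimated correlation was 0.86 for ciliated cell markers. The simulated list counts therefore do not give the rate of false calls here. With the 6 day 0 arrays split so that HE and SE were mixed, camera called up to 13 lists. A list shifted by 0.5 was recovered in 4 contrasts but not in SE over HE on day 7 (adjusted p = 0.162) or in the interaction (adjusted p = 0.678).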

Results

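The arrays profiled endometrium and embryos of cows with and without subclinical endometritis, an inflammation of the uterine lining without outward signs that is recognised by neutrophils on a cytobrush. Endometrium came from 3 HE and 3 SE pools at insemination (day 0) and from 2 HE and 3 SE pools at flushing (day 7). Blastocysts recovered on day 7 came from 2 pools of HE and 3 pools of SE donors. Median signals ran from 4.18 to 4.30 on the log2 scale over the endometrium arrays and from 3.08 to 3.12 over the blastocyst arrays. Each array had 12303 to 12471 probe sets above the filter in endometrium and 10823 to 10877 in blastocysts. Replicates were pools, so the p-values measure the spread between these pools, not between cows.

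SE and HE endometrium were first compared on day 0, to find what distinguished an inflamed uterus at insemination. PDZK1, a scaffold protein of the apical epithelial membrane and a known oestrogen target, was 4.03-fold lower in SE. It averaged 8.79 ± 0.30 (SD, n = 3) in HE and 6.78 ± 0.13 (SD, n = 3) in SE, and it fell by 2.01 (standard error 0.19, adjusted p = 0.0139), with each SE pool below each HE pool. On day 7 it stood at 13.10 ± 0.31 (SD, n = 2) in HE and 13.22 ± 0.18 (SD, n = 3) in SE. The transcript behind probe set Bt.15970.1.A1_at, with no gene named here, rose from 3.90 ± 0.05 to 7.80 ± 1.19 (SD, n = 3 each; adjusted p = 0.0274). A probe set annotated to EED, a Polycomb subunit, rose by 1.31 (standard error 0.14, adjusted p = 0.0259), but 20 kept probe sets carry that symbol. Their changes ran from -1.30 to 1.31, with 9 higher and 11 lower, and the mean over them was -0.03 (adjusted p = 0.963). These were the 3 probe sets called by limma, 2 higher and 1 lower, while 1020 had an unadjusted p under 0.05 against 671 expected by chance. The calls of EED and of the unnamed transcript were kept, among single pools left out, only without SE replicate 1 or SE replicate 2. The PDZK1 call was lost without HE replicate 1 (-1.91, adjusted p = 0.0648) or HE replicate 3 (-1.94, adjusted p = 0.0631), and over all pools left out in turn the count ran from 0 without HE replicate 3 to 11 without SE replicate 1. Fitted on the 6 day 0 arrays alone, PDZK1 had an adjusted p = 0.285. Its call was also lost with SE replicate 2 and day 7 HE replicate 1 left out together. With no filter on low values 2 of the 3 calls were kept, and with the replicate number as a block 0 were.

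Genes of neutrophil inflammation gave higher means in SE on day 0 with a wide spread between pools. Status was itself set by polymorphonuclear cells on the brush, so this direction is not independent of the grouping. S100A8, a subunit of the neutrophil alarmin calprotectin, read 9.07, 9.39 and 12.59 in the SE pools and 9.58, 6.31 and 6.19 in the HE pools, a difference of 2.99 (standard error 1.15, adjusted p = 0.61). Differences were 2.84 for its partner S100A9, 1.76 for S100A12, 2.97 for the cytokine IL1B and 1.89 for the neutrophil attractant CXCL8, none past the test. Beyond these, LYZ2, a lysozyme, stood at 7.12 ± 0.19 in HE and 8.46 ± 0.01 in SE (SD, n = 3 each; adjusted p = 0.161), and S100A14, a calcium-binding protein of epithelia, at 7.46 ± 0.40 and 9.14 ± 0.37 (adjusted p = 0.193). CTSC, the protease that activates neutrophil serine proteases, differed by 1.12 (adjusted p = 0.292), and PSTPIP2, a cytoskeletal adaptor of myeloid cells, by 0.76 (adjusted p = 0.204) from an HE level of 3.20, below the filter. On the lower side in SE were GPLD1, a phospholipase that releases lipid-anchored proteins, at 6.68 ± 0.61 against 8.60 ± 0.44 (SD, n = 3 each; adjusted p = 0.161), the epithelial integrin ITGB6 (-0.84, adjusted p = 0.161), AFG1L (-0.89, adjusted p = 0.172) and the lipase DDHD2 (-1.06, adjusted p = 0.196). PTGS2, the inducible prostaglandin synthase, differed by -0.42, the oxytocin receptor OXTR by -0.18 and the uterine secretory protein SERPINA14 by -0.44, none past the test. GPLD1 passed only without SE replicate 1 (-2.25, adjusted p = 0.0286), and the sign of PTGS2 turned without SE replicate 2 (0.09).

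**Figure D1:**
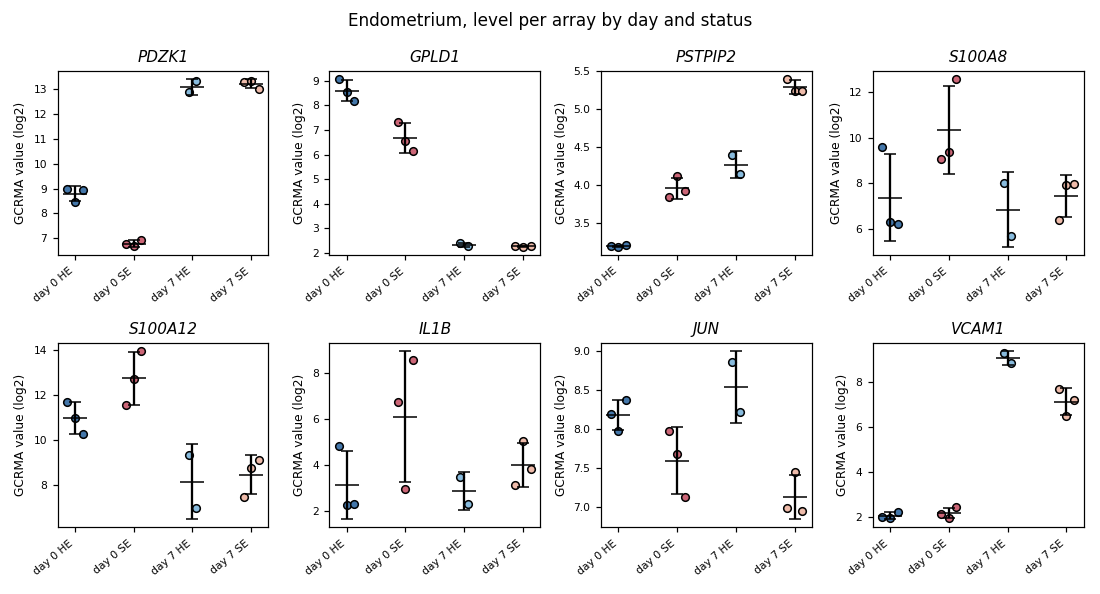
GCRMA level (log2) of 8 genes in endometrium, by day and status; each point is an array, the dash its group mean and the bar the SD. PDZK1 separates the day 0 groups, at 8.79 in HE and 6.78 in SE, whereas S100A8, S100A12 and IL1B overlap between pools.

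As groups, 15 of the 28 lists tested were higher in SE on day 0 and 0 were lower; camera called them at the preset correlation, and with an estimated correlation or with fry 0 were called. Ciliated cell markers were shifted furthest, with 8 of 8 members higher and a median of 1.21 (adjusted p = 5.51e-08; adjusted p = 0.295 with an estimated correlation). They include DYNLRB2, a light chain of ciliary dynein, at 1.39 and SPAG6, part of the axoneme's central pair, at 0.99. Neutrophil markers had 11 of 12 members higher (median 0.52, adjusted p = 1.71e-04; adjusted p = 0.295 with an estimated correlation). Inflammatory cytokines and chemokines had 16 of 19 higher (median 0.45, adjusted p = 4.51e-04; adjusted p = 0.295 with an estimated correlation), among them CXCL5 at 1.43 and IL1A at 1.55. Macrophage and dendritic cell markers had 8 of 10 higher (median 0.45, adjusted p = 0.00777; adjusted p = 0.423 with an estimated correlation), with AIF1 at 0.84 and LAPTM5 at 0.43. Antigen presentation had 17 of 24 higher (median 0.23, adjusted p = 8.28e-04; adjusted p = 0.423 with an estimated correlation), led by the class II genes BOLA-DRA (0.92) and BOLA-DRB3 (0.85). Matrix remodelling had 15 of 21 higher (median 0.44, adjusted p = 0.0077; adjusted p = 0.295 with an estimated correlation), with the urokinase receptor PLAUR at 1.43 and the protease inhibitor TIMP1 at 0.63. Adjusted over the list alone, 1 matrix gene passed, against 0 over all genes tested. These 6 lists were called whichever pool was left out, but without SE replicate 2 the medians were 0.64 for ciliated cells, 0.30 for cytokines, 0.12 for antigen presentation and 0.87 for neutrophils. Without HE replicate 1 the neutrophil median was 0.85, and without SE replicate 1 that of matrix remodelling was 0.25. With no filter on low values the calls stood, with medians of 0.02 for neutrophils, 0.19 for macrophages, 0.19 for cytokines and 0.22 for matrix remodelling.

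The other lists higher in SE on day 0 leaned on single pools. The EIF4E control, 3' minus 5', a sign of RNA quality, was higher in each SE pool (3.88 to 4.27) than in each HE pool (3.70 to 3.85) on day 0. The same difference for cyclophilin (0.64 to 0.98 in HE, 0.74 to 1.17 in SE) and for GAPDH overlapped between the groups. Day 0 SE replicate 2 stood apart: its mean correlation with the other day 0 arrays was 0.961, against 0.975 to 0.979 for the others, and its GAPDH control, 3' minus 5', read 0.578 against 0.0264 to 0.141. Antimicrobial and acute phase proteins had 16 of 16 members higher (median 0.54, adjusted p = 3.21e-05; adjusted p = 0.295 with an estimated correlation), including the defensins TAP (2.31) and EBD (1.88). Adjusted over the list alone, 1 of them passed, against 0 over all genes tested; without SE replicate 2 the median was 0.17 (adjusted p = 0.0507), and without SE replicate 3 it was 0.91. Mucins and secretory epithelium had 11 of 12 higher (median 0.81, adjusted p = 4.33e-05; adjusted p = 0.409 with an estimated correlation), with the goblet cell protein CLCA1 at 3.15 and the water channel AQP3 at 1.64. Without SE replicate 2 that median was 0.30 (adjusted p = 0.214), and without HE replicate 2 it was 1.25. The unfolded protein response (13 of 17 higher, adjusted p = 0.0163; PDIA4 0.46 and -0.14 on its 2 probe sets, SEC61B 0.23) had a median of 0.10 with that pool and -0.01 without it (adjusted p = 0.539), and 0.26 without SE replicate 3. Stromal fibroblast markers had 14 of 15 higher (median 0.66, adjusted p = 5.65e-04; VIM 0.83, MGP 0.88, with the other 3 MGP probe sets lower) and a median of 0.28 without HE replicate 2 (adjusted p = 0.127), 0.39 without SE replicate 1 and 1.06 without HE replicate 3. With an estimated correlation the adjusted p = 0.423 for both of these lists.

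On day 0, 5 further lists were called. The IGF system and imprinted genes (16 of 20 higher, median 0.32, adjusted p = 0.0222; ASCL2 0.92, IGFBP6 0.83) had medians of 0.11 without HE replicate 1 (adjusted p = 0.180) and 0.10 without SE replicate 2 (adjusted p = 0.182). The complement system (7 of 10, median 0.31, adjusted p = 0.0269; CFB 1.06, CFD 1.49) was lost without HE replicate 2 (0.49, adjusted p = 0.0688), HE replicate 3 (0.21, adjusted p = 0.0714) or SE replicate 2 (0.19, adjusted p = 0.330). Epithelial markers (12 of 18, median 0.15, adjusted p = 0.0284; CLDN3 0.36, KRT19 0.62) were lost without HE replicate 1 (0.06, adjusted p = 0.0795), HE replicate 3 (0.15, adjusted p = 0.0707) or SE replicate 2 (0.05, adjusted p = 0.274). Interferon-stimulated genes (18 of 30, median 0.05, adjusted p = 0.0335; SAMD9 1.48, IFITM1 0.58) and lymphocyte markers (12 of 17, median 0.15, adjusted p = 0.0340; JCHAIN 2.18, CD3D 0.76) were lost without HE replicate 1 (adjusted p = 0.207 and 0.145), HE replicate 2 (adjusted p = 0.0688 and 0.112), SE replicate 1 (adjusted p = 0.158 and 0.0684) or SE replicate 2 (adjusted p = 0.184 and 0.284), with medians of 0.002 to 0.06 and 0.02 to 0.15. Over all pools left out in turn the highest medians were 0.13 and 0.25 for these lists and 0.54 for the complement system. With an estimated correlation the adjusted p = 0.423 for the IGF and complement lists, 0.382 for epithelial markers, 0.565 for interferon-stimulated genes and 0.652 for lymphocyte markers. With no filter on low values the calls of the IGF list (median 0.03, adjusted p = 0.0687), the complement system (0.03, adjusted p = 0.0661) and lymphocyte markers (0.04, adjusted p = 0.143) were lost. Array weights ended those of the unfolded protein response (0.05, adjusted p = 0.13), the complement system (0.20, adjusted p = 0.13), epithelial markers (0.13, adjusted p = 0.120) and lymphocyte markers (0.21, adjusted p = 0.0882). Gene means ended that of epithelial markers (0.11, adjusted p = 0.0868), and a further quantile normalization that of lymphocyte markers (0.21, adjusted p = 0.0802). Leaving out SE replicate 2 kept 7 of the 15 lists.

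Of the lists not called on day 0, oestrogen-responsive genes (adjusted p = 0.204) held PDZK1, their only member past the threshold. Luteal phase and progesterone-responsive genes (adjusted p = 0.255) had 1 member lower adjusted over the list alone, and prostaglandin synthesis and signalling (adjusted p = 0.969) had 1 higher, each against 0 over all genes tested. Toll-like receptor and NF-kB signalling (adjusted p = 0.180), glycolysis (0.204), heat shock and protein folding (0.191), immediate-early genes (0.191), oxidative stress response (0.366) and cholesterol and fatty acid synthesis (0.447) did not pass. Nor did cell cycle (adjusted p = 0.626), oxidative phosphorylation (0.860), apoptosis (0.969) or cytosolic ribosomal proteins (0.977).

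**Figure D2:**
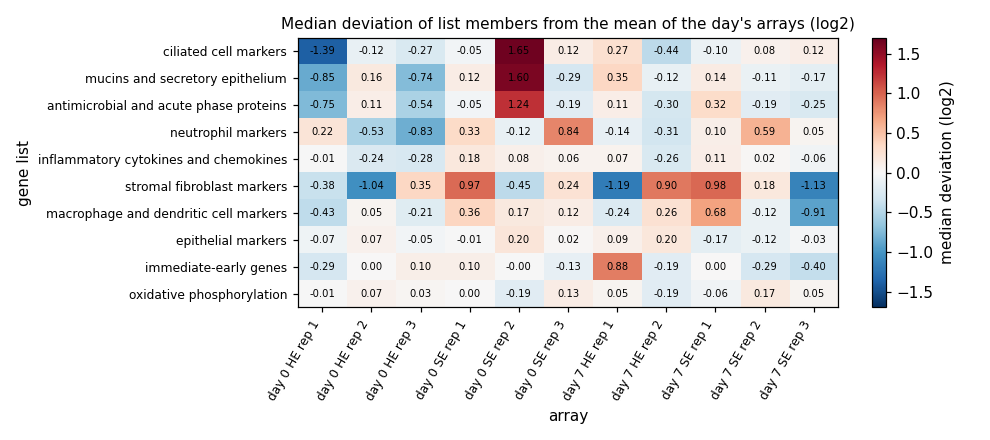
Median deviation (log2) of the members of 10 gene lists from the mean of the day's arrays, per endometrium array. Day 0 SE replicate 2 reaches 1.65 for ciliated cell markers and 1.60 for mucins.

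On day 7, when the embryos were flushed, the same contrast asked which differences accompanied them. The class II gene BOLA-DQA5 stood at 5.99 ± 0.55 (SD, n = 2) in HE and 3.89 ± 0.19 (SD, n = 3) in SE (-2.10, adjusted p = 0.166). Its SE mean lay below the filter. The 2 probe sets of BOLA-DQA1, another class II gene, had higher means in SE (0.42 and 0.49). VCAM1, an adhesion molecule for leukocytes, stood at 9.08 ± 0.30 (SD, n = 2) and 7.15 ± 0.59 (SD, n = 3), a difference of -1.93 (adjusted p = 0.166). PSTPIP2 went the other way, from 4.27 ± 0.18 (SD, n = 2) to 5.29 ± 0.09 (SD, n = 3), a difference of 1.02 (standard error 0.15, adjusted p = 0.155). limma called 0 of 13421 probe sets, with 477 at an unadjusted p under 0.05 against 671 expected by chance, so these are values, not changes. With no filter on low values 10 probe sets passed, PSTPIP2 among them (adjusted p = 0.0312). Counts of up to 2 were reached without day 7 HE replicate 2 or SE replicate 1.

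Other genes with the smallest p on day 7 were GPATCH2L (1.23, adjusted p = 0.250), the nuclear pore protein NUP42 (0.70, adjusted p = 0.464), the p38 kinase MAPK12 (1.00, adjusted p = 0.491) and DTNBP1 (0.73, adjusted p = 0.504), all with higher means in SE. With lower means were the basement membrane collagen COL4A3 (-0.94, adjusted p = 0.488) and the AP-1 subunit JUN (-1.40, adjusted p = 0.488). S100A8 read 6.83 ± 1.64 (SD, n = 2) in HE and 7.42 ± 0.92 (SD, n = 3) in SE on day 7, and its difference of 0.59 turned to -0.58 without HE replicate 2. Differences of 0.64 for S100A9 and 0.31 for S100A12 turned to -0.24 and -0.87 without the same pool, and that of S100A12 to -0.03 without SE replicate 3. IL1B differed by 1.11, CXCL8 by 2.30, OXTR by -0.42, PTGS2 by -0.29 and SERPINA14 by 0.57, none past the test. Without HE replicate 2 the signs of OXTR (0.21) and PTGS2 (0.30) turned, and that of OXTR also without SE replicate 1 (0.19).

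On day 7 camera called 7 of 28 lists, 5 lower and 2 higher in SE, and 0 with an estimated correlation or with fry. The EIF4E control, 3' minus 5', again lay higher in each SE pool (4.05 to 4.52) than in each HE pool (3.67 and 3.91). The cyclophilin control (0.85 and 1.23 in HE, 0.89 to 1.12 in SE) and the GAPDH control (0.273 and 0.389, 0.215 to 0.574) overlapped. Epithelial markers were lower in 18 of 18 members (median -0.26, adjusted p = 3.43e-06; adjusted p = 0.109 with an estimated correlation), with the protease inhibitor SPINT1 at -0.46 and E-cadherin, CDH1, at -0.48. This list was called whichever pool was left out. Immediate-early genes, transcription factors and regulators induced within minutes of a stimulus, were lower in 20 of 23 members (median -0.57, adjusted p = 2.02e-09; adjusted p = 0.304 with an estimated correlation). Without HE replicate 1, however, their median was -0.04 (adjusted p = 0.374), and without HE replicate 2 it was -1.10. Oestrogen-responsive genes were lower in 9 of 15 (median -0.22, adjusted p = 0.0112; adjusted p = 0.209 with an estimated correlation), with the matricellular protein CCN1 at -1.68 and the secretory chaperone AGR2 at -0.89. Their median was 0.004 without HE replicate 1 (adjusted p = 0.250), -0.18 without SE replicate 2 (adjusted p = 0.174) and -0.02 without HE replicate 2.

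Antigen presentation was lower on day 7 in 18 of 24 members (median -0.22, adjusted p = 2.15e-04; adjusted p = 0.591 with an estimated correlation), with BOLA-DQA5 at -2.10 and the peptide-trimming enzyme ERAP1 at -1.35. Adjusted over the list alone, 1 gene was lower, against 0 over all genes tested. The median was -0.13 without HE replicate 2 (adjusted p = 0.114), 0.02 without SE replicate 3 (adjusted p = 0.407) and -0.34 without SE replicate 1. The complement system was lower in 9 of 10 (median -0.38, adjusted p = 0.00900; adjusted p = 0.591 with an estimated correlation), with the secreted chaperone CLU at -0.49 and the alternative-pathway factor CFB at -0.68. It was lost without HE replicate 2 (median -0.46, adjusted p = 0.0711), SE replicate 2 (median -0.38, adjusted p = 0.132) or SE replicate 3 (median -0.17, adjusted p = 0.407), and its median was -0.22 without HE replicate 1. Oxidative phosphorylation was higher in 62 of 73 (median 0.14, adjusted p = 3.78e-04; adjusted p = 0.880 with an estimated correlation), with the complex I subunits NDUFB5 at 0.39 and NDUFB6 at 0.27. The median was 0.002 without HE replicate 2 (adjusted p = 0.914), 0.08 without SE replicate 2 (adjusted p = 0.132) and 0.24 without HE replicate 1. Neutrophil markers were higher in 11 of 12 (median 0.49, adjusted p = 0.0436; adjusted p = 0.605 with an estimated correlation), with PLEK at 1.78 and G0S2 at 1.32. That call was lost without HE replicate 1 (median 0.45, adjusted p = 0.227; G0S2 -0.002), HE replicate 2 (0.25, adjusted p = 0.0677), SE replicate 1 (0.75, adjusted p = 0.128) or SE replicate 2 (0.19, adjusted p = 0.290). With no filter on low values the calls of the neutrophil (median 0.04, adjusted p = 0.139), complement (-0.03, adjusted p = 0.0807) and oestrogen (-0.02, adjusted p = 0.0925) lists were lost. That of neutrophils was also lost with array weights (0.49, adjusted p = 0.120), median centring (0.54, adjusted p = 0.0764) or a filter at log2 above 5 (0.40, adjusted p = 0.0721). Toll-like receptor and NF-kB signalling (adjusted p = 0.144) had 1 member lower adjusted over the list alone.

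Day 7 was then compared with day 0 within each status, spanning the time from oestrus into the luteal phase of superovulated cows. Insemination, the first brushing and the arrival of embryos also set the days apart, so these and the cycle stage cannot be told apart. LPL, the lipase that frees fatty acids from lipoproteins, rose from 2.67 ± 0.23 (SD, n = 3) to 9.53 ± 0.30 (SD, n = 2) in HE and from 2.54 ± 0.12 to 10.35 ± 0.26 (SD, n = 3 each) in SE. RBP4, the carrier of retinol, fell from 11.77 ± 0.31 (SD, n = 3) to 3.64 ± 0.20 (SD, n = 2) in HE and from 11.28 ± 0.04 to 3.66 ± 0.13 (SD, n = 3 each) in SE. Other genes that rose were the proline-degrading enzyme PRODH (8.77 in HE, 9.31 in SE), the aminopeptidase ANPEP (8.25, 7.93), the serine-synthesis enzyme PHGDH (6.83, 9.11), the ferric reductase CYBRD1 (7.46, 8.36) and the triglyceride-synthesis enzyme DGAT2 (5.52, 6.48). Also among the largest rises in HE or SE were the endothelins EDN3 (8.39, 9.62) and EDN1 (6.90 in HE), VCAM1 (7.01, 4.95) and the kinetochore gene SPC24 (6.58, 7.46). Others were the amino acid transporter SLC6A20 (7.58 in HE), the fatty acid transporter SLC27A6 (7.26 in SE) and the lysosomal channel MCOLN3 (6.92 in SE).

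Among the largest falls from day 0 to day 7, the protease inhibitor SERPINA1 changed by -9.08 in HE and -9.11 in SE and the mucus glycoprotein OLFM4 by -8.61 and -9.29. Falls followed in the plasma glycoprotein AHSG, by -7.75 and -6.94 (at the least -0.34 and -0.14 on its 6 probe sets, 4 of them called), and in SERPINA14 (-6.52, -5.52). SPINK1, a trypsin inhibitor (-6.91), the defensin EBD (-6.71) and the endotoxin-binding protein LBP (-6.73) were among the largest falls in SE, and LBP changed by -5.78 in HE. The crystallin CRYGS (-9.74, -7.71), the secreted kinase PKDCC (-7.33, -6.85) and SMPX (-7.32, -7.49) fell in both, and NPL (-7.12) and EHD3 (-6.48, and -2.44 on its other probe set) were among the largest falls in HE. OXTR, through which oxytocin acts on the uterus, changed by -5.65 and -5.89. PTGS2 changed by -2.21 (adjusted p = 0.00632) in HE and -2.08 (adjusted p = 0.00407) in SE, and S100A12 by -2.83 (adjusted p = 0.0189) and -4.28 (adjusted p = 9.10e-04). The HE calls were lost for PTGS2 without day 7 HE replicate 1 (-1.62, adjusted p = 0.0685) and for S100A12 without day 0 HE replicate 1 (-2.48, adjusted p = 0.0596) or day 7 HE replicate 2 (-1.66, adjusted p = 0.196), or with no filter (adjusted p = 0.0606). S100A8 differed by -0.52 in HE and -2.93 in SE, S100A9 by -0.72 and -2.92, IL1B by -0.25 and -2.11, and CXCL8 by -1.62 and -1.21, none past the test. In HE these 4 signs turned without day 7 HE replicate 2 (0.64, 0.17, 0.34 and 0.25), and all but that of CXCL8 turned without day 0 HE replicate 1. In SE, S100A9 (-3.88, adjusted p = 0.0379) and IL1B (-3.67, adjusted p = 0.00824) passed without SE replicate 2 of day 0, and S100A8 without SE replicate 1 (-3.57, adjusted p = 0.0457). Without day 0 HE replicate 1, which enters through the pooled spread, S100A8 and S100A9 passed as well (adjusted p = 0.0307 and 0.0393). So did S100A8 with an intensity trend (0.0486) or the SE arrays alone (0.0459) and IL1B with array weights (-2.95, adjusted p = 0.0406).

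Between the days limma called 6034 of 13421 probe sets in HE (45.0%), 2920 higher and 3114 lower, and 6723 in SE (50.1%), 3485 higher and 3238 lower. Of these, 1954 rose and 1854 fell more than 2-fold in HE, and 2077 and 1910 in SE. The changes in HE and SE had a Pearson r of 0.947 across probe sets, with the same sign in 88.4%. Higher in both were 2627 probe sets, where independent choices would share 758, lower in both 2552 against 751, and 1 was called in opposite directions.

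**Figure D3:**
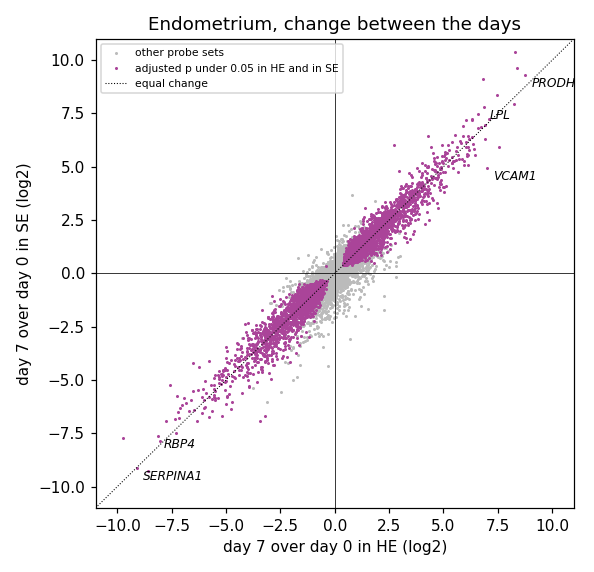
Change between the days (log2) of each kept probe set in HE (x axis) and SE (y axis), with the line of equal change. The 2627 probe sets higher in both and the 2552 lower in both are coloured; LPL and PRODH lie at the upper right, SERPINA1 and RBP4 at the lower left.

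Of the 28 lists, camera called 1 between the days in HE and 3 in SE. Oxidative phosphorylation rose in HE, with 34 of 73 members up and 3 down (median 0.43, adjusted p = 6.73e-06; adjusted p = 0.995 with an estimated correlation), and in SE, with 55 up and 1 down (median 0.58, adjusted p = 3.66e-08; adjusted p = 0.974 with an estimated correlation). Examples were the complex I subunit NDUFB6 (1.64, 2.12) and the ATP synthase subunit ATP5MC1 (1.71, 1.95). Of the cell type markers in HE, epithelial markers had a median of -0.86 and passed by fry (adjusted p = 0.00118), not by camera (adjusted p = 0.343). Macrophage markers had a median of 1.30 (camera adjusted p = 0.385, fry adjusted p = 0.180) and were not called. Nor were lymphocyte markers, with a median of 0.98 (camera adjusted p = 0.221, fry adjusted p = 0.185). The GAPDH control, 3' minus 5', was higher in each day 7 HE pool (0.273 and 0.389) than in each day 0 HE pool (0.0560 to 0.141). Between these days in HE the cyclophilin control (0.85 and 1.23 on day 7, 0.64 to 0.98 on day 0) overlapped. So did the EIF4E control (3.67 and 3.91, 3.70 to 3.85). In SE the poly-A spike controls were higher in each day 7 pool (8.94 to 9.32) than in each day 0 pool (8.13 to 8.82). Medians in SE were -1.23 for ciliated cell markers (camera adjusted p = 0.133) and 0.84 for lymphocyte markers (camera adjusted p = 0.198). In SE, antimicrobial and acute phase proteins fell, with 11 of 16 members down and 1 up (adjusted p = 0.0146; adjusted p = 0.907 with an estimated correlation). Epithelial markers fell in SE too, with 13 of 18 down and 3 up (adjusted p = 0.0178; adjusted p = 0.538 with an estimated correlation), including the keratins KRT7 (-3.95) and KRT18 (-2.61). Both calls were lost without day 0 SE replicate 2 (medians -1.54 and -0.87 against -2.11 and -0.85; adjusted p = 0.0704 and 0.0541). The antimicrobial one was also lost with no filter (-1.04, adjusted p = 0.0509) or gene means (-1.63, adjusted p = 0.0632). These falls were not particular to SE. In HE the antimicrobial list had a median of -1.32, with 8 members down and 0 up (camera adjusted p = 0.221, fry adjusted p = 0.00709). Epithelial markers had 9 members down and 4 up in HE, and the keratins fell there as well (-3.13 and -2.16). Luteal phase and progesterone-responsive genes, fixed from known markers, had 12 of 38 members up and 14 down in HE and 13 up and 15 down in SE. The list did not pass by camera (adjusted p = 0.993 and 0.747). Its members moved both ways, so a test for 1 direction cannot show whether the list responded. fry, which does not compare a list with other genes, called 10 lists in HE and 11 in SE. The luteal list was among them, as lower (adjusted p = 0.00709 and 0.0315), although its median was 2.94e-04 in HE and -0.27 in SE.

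Single members of other lists changed in either direction between the days. In the prostaglandin list the prostacyclin synthase PTGIS (5.18 in HE, 5.64 in SE) and the receptor PTGER4 (4.83, 4.31) rose, while the receptor PTGER2 (-3.85, -3.80) and the aldo-keto reductase AKR1C4 (-5.19, -5.02) fell, the latter on 2 of its 4 probe sets, which ran up to -1.17 in HE and 0.23 in SE. In the IGF list the insulin receptor INSR (3.91, 3.62) and the imprinted transcription factor ASCL2 (4.74, 3.09) rose and the binding protein IGFBP3 (-5.50, -5.53) fell. PDZK1 rose by 4.31 in HE and 6.45 in SE. The endotoxin receptor TLR4 (-3.03, -3.34), the urokinase receptor PLAUR (-3.76, -4.70), the cell cycle inhibitor CDKN1A (-4.72, -5.06) and the stress-induced IER3 (-4.98, -4.85) fell in both. Some lists not called by camera were lower by fry. Matrix remodelling was lower in HE (adjusted p = 0.00450) and SE (adjusted p = 2.82e-05). In HE, apoptosis (adjusted p = 0.00115) and Toll-like receptor and NF-kB signalling (adjusted p = 0.0150) were lower by fry. In SE, immediate-early genes were (adjusted p = 0.0170). The fucosyltransferase FUT2 (-4.77, -6.37) and, in HE, AGR2 (-2.66) fell, while mucins and secretory epithelium did not pass by camera (adjusted p = 0.529 in HE and 0.0665 in SE). By fry that list was lower in SE (adjusted p = 0.0225), with 7 of 12 members lower and 1 higher. The redox enzyme TXNRD1 (3.18, 2.95), the lipid regulator SREBF1 (2.15, 2.30) and the mitotic cyclin CCNB1 (4.15, 5.10) rose, and the sterol enzyme HMGCS1 (-2.15, -1.65) and the lactate transporter SLC16A1 (-5.78, -4.11) fell. LYZ2 is left open: the probe set that stood for it fell by 3.81 in SE, but 3 of its 4 kept probe sets rose, and the mean over them rose by 1.79 (adjusted p = 0.00419).

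The interaction asked whether the status difference was another on day 7 than on day 0. PDZK1 had the smallest p, with 2.14 (standard error 0.29, adjusted p = 0.195), its difference lying at -2.01 on day 0 and 0.13 on day 7. GPATCH2L followed with 2.04 (adjusted p = 0.195), and SPX, a secreted neuropeptide (1.32, adjusted p = 0.513), DTNBP1 (1.13, adjusted p = 0.513) and NUP42 (0.92, adjusted p = 0.567) were also more positive on day 7. EED (-1.37 for 1 of its 20 probe sets, adjusted p = 0.286), CTSC (-1.65, adjusted p = 0.521), VCAM1 (-2.06, adjusted p = 0.567), BOLA-DQA5 (-2.09, adjusted p = 0.629) and the chloride channel CFTR (-0.82, and 0.22 on its second probe set) were more negative. limma called 0 probe sets, with 526 at an unadjusted p under 0.05 against 671 expected by chance, and 2 were called without day 7 SE replicate 1. S100A8 gave -2.41, S100A9 -2.20, S100A12 -1.45, IL1B -1.86, CXCL8 0.41, PTGS2 0.12, OXTR -0.25 and SERPINA14 1.00, none past the test. The signs of CXCL8, PTGS2 and OXTR depended on the pools used.

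As groups, 14 of 28 lists differed between the days by camera, 13 of them more negative on day 7 and oxidative phosphorylation more positive. The epithelial markers (median -0.40, adjusted p = 1.18e-06; adjusted p = 0.0779 with an estimated correlation), antigen presentation (-0.49, adjusted p = 1.49e-07; adjusted p = 0.267 with an estimated correlation) and the complement system (-0.63, adjusted p = 1.70e-04; adjusted p = 0.267 with an estimated correlation) were called whichever pool was left out. So were ciliated cell markers (-1.13, adjusted p = 1.60e-05) and mucins (-1.16, adjusted p = 4.20e-05), each with an adjusted p = 0.324 with an estimated correlation. With day 0 SE replicate 2 and day 7 HE replicate 1 both left out, however, their medians were -0.16 (adjusted p = 0.202) and -0.16 (adjusted p = 0.374). Over single pools left out, the median ran from -1.49 to -0.63 for ciliated cells, -1.52 to -0.48 for mucins, -0.66 to -0.30 for antigen presentation and -1.45 to -0.42 for the complement system. With an estimated correlation, or with fry, 0 of the 14 were called. With no filter on low values the 14 calls stood, but the median over the list medians was -0.16, against -0.53 with the filter. The status changes of the days had a Pearson r of 0.116 across probe sets, with the same sign in 53.2%, and r was -2.76e-04 without day 7 SE replicate 1 and 0.212 without day 7 SE replicate 3.

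Blastocysts of SE and HE donors were compared to ask whether the state of the uterus was reflected in the embryo. GZMB, the protease granzyme B, stood at 4.79 ± 0.17 (SD, n = 2) in HE embryos and at the floor of the scale in SE embryos (n = 3), so that the difference of -2.59 (adjusted p = 0.117) is a lower bound on its size. The zinc finger gene ZNF165 stood at 8.53 ± 0.12 (SD, n = 2) and 6.06 ± 0.17 (SD, n = 3), a difference of -2.47 (adjusted p = 0.131). TCEAL4, a protein related to elongation factors, stood at 6.74 ± 0.14 (SD, n = 2) and 8.40 ± 0.14 (SD, n = 3), a difference of 1.66 (adjusted p = 0.243). limma called 0 of 11014 probe sets, with 1029 at an unadjusted p under 0.05 against 551 expected by chance. With all 16 arrays in 1 fit, where the endometrium sets most of the spread, 473 passed, GZMB, ZNF165 and TCEAL4 among them.

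Other blastocyst genes with the smallest p were ADD3, which caps actin filaments (1.52, adjusted p = 0.243), DECR1, an enzyme of fatty acid oxidation (1.54, adjusted p = 0.256), GPLD1 (1.92, adjusted p = 0.271) and RPUSD3 (1.15, adjusted p = 0.271), higher in SE. Lower were BZW1 (-1.61, adjusted p = 0.243), GSDMC, a pore-forming gasdermin (-1.67, adjusted p = 0.243), and the nucleolar protein NOLC1 (-2.10, adjusted p = 0.243). The second kept probe set of BZW1 gave 0.04, that of NOLC1 0.38 and that of RPUSD3 -0.96, and the 3 of ADD3 ran from 0.08 to 1.52. Lineage genes did not pass: the pluripotency factors POU5F1 (-0.66, adjusted p = 0.574) and SOX2 (-0.41) and the hypoblast factor GATA6 (0.03). Nor did the trophectoderm genes KRT18 (0.09), IFNT2 (-0.41) and PAG2 (0.35). The sex-linked gene XIST did not pass either (0.32 to 0.46 on its 3 probe sets). The signs of KRT18, IFNT2, PAG2 and GATA6 depended on the pools used. As lists, trophectoderm genes (adjusted p = 0.162), inner cell mass and pluripotency genes (0.510), hypoblast genes (0.0903) and chromatin and DNA methylation regulators (0.452) did not pass.

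In blastocysts 3 of 20 lists were lower in SE by camera, and 0 with an estimated correlation or with fry. Oxidative phosphorylation was lower in 51 of 73 members (median -0.13, adjusted p = 0.0104; adjusted p = 0.676 with an estimated correlation), with ATP5ME of ATP synthase at -0.66 and UQCR10 of complex III at -0.44. The unfolded protein response was lower in 12 of 17 (median -0.16, adjusted p = 0.0283; adjusted p = 0.637 with an estimated correlation), with HERPUD1 at -0.95 and the ubiquitin ligase SYVN1 at -0.66. Cytosolic ribosomal proteins were lower in 50 of 61 (median -0.08, adjusted p = 0.0283; adjusted p = 0.677 with an estimated correlation), with RPL29 at -0.61 and RPS7 at -0.40, although the other RPS7 probe sets were higher. The oxidative phosphorylation call was lost without HE replicate 2 (median -0.10, adjusted p = 0.101) or SE replicate 1 (median -0.10, adjusted p = 0.0628). That of the unfolded protein response was lost without HE replicate 2 (median -0.08, adjusted p = 0.196), SE replicate 2 (median -0.14, adjusted p = 0.0658) or SE replicate 3 (median -0.10, adjusted p = 0.0908), with a median of -0.30 without HE replicate 1. That of ribosomal proteins was lost without HE replicate 1 (median -0.04, adjusted p = 0.232), SE replicate 1 (-0.09, adjusted p = 0.0998) or SE replicate 2 (-0.07, adjusted p = 0.0651), with a median of -0.12 without HE replicate 2. Control probe sets differed between the same groups: the poly-A spike controls averaged 11.80 ± 0.31 (SD, n = 2) in HE and 10.46 ± 0.28 (SD, n = 3) in SE. With the spike level as a covariate the medians were -0.15 for oxidative phosphorylation (adjusted p = 0.206), -0.21 for ribosomal proteins (adjusted p = 0.113) and 0 for the unfolded protein response (adjusted p = 0.849). With gene means the ribosomal (-0.07, adjusted p = 0.184) and unfolded protein (-0.16, adjusted p = 0.0515) calls were lost. Median centring ended the same calls (-0.06, adjusted p = 0.0596, and -0.15, adjusted p = 0.05004). A further quantile normalization ended the ribosomal one (-0.09, adjusted p = 0.0650). With all 16 arrays in 1 fit the medians were unchanged and all 3 calls were lost (adjusted p = 0.0522 to 0.0544). The GAPDH control, 3' minus 5', read 5.04 ± 0.10 (SD, n = 2) and 5.68 ± 0.19 (SD, n = 3).

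**Figure D4:**
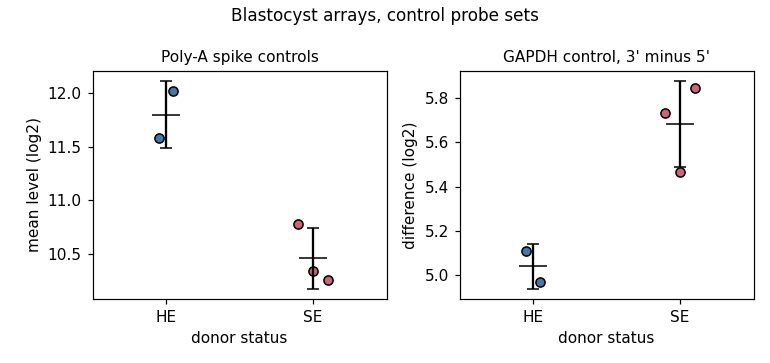
Mean level (log2) of the 12 poly-A spike probe sets and the 3' minus 5' difference (log2) of the GAPDH control on the 5 blastocyst arrays; points are arrays, dashes group means and bars the SD. The spikes average 11.80 in HE and 10.46 in SE, without overlap.

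The remaining blastocyst lists did not pass: inflammatory cytokines and chemokines (adjusted p = 0.0740), cell cycle (0.162), cholesterol and fatty acid synthesis (0.162), immediate-early genes (0.182), stromal fibroblast markers (0.360), Toll-like receptor and NF-kB signalling (0.458), oxidative stress response (0.510), prostaglandin synthesis (0.510), apoptosis (0.534), the IGF system (0.534), interferon-stimulated genes (0.614), heat shock (0.819) and glycolysis (0.862). Across the 9795 probe sets kept in both tissues, the status changes of day 7 endometrium and blastocysts had a Pearson r of -0.0124. Over the pools left out in turn that r ran from -0.0640 without day 7 SE replicate 1 to 0.0323 without day 7 HE replicate 2.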

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

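The tests weighing day 0 SE replicate 2, day 7 HE replicate 1, the blastocyst pools and the control probe sets as explanations, and the removal of both pools together, were chosen after the results were seen; leaving out each pool in turn and the splits of the arrays were set in advance.

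A difference between the days in the SE over HE change, by camera's test of the interaction, marked 14 gene lists; each value is the median of its members, day 7 minus day 0. With an estimated correlation 0 were called (adjusted p of 0.0779 to 0.845). With no filter on low values the 14 calls stood, but the median over the list medians was -0.16, against -0.53 with the filter. Called whichever single pool was left out were epithelial markers (-0.40, adjusted p = 1.18e-06), antigen presentation (-0.49, adjusted p = 1.49e-07), the complement system (-0.63, adjusted p = 1.70e-04), ciliated cell markers (-1.13, adjusted p = 1.60e-05) and mucins and secretory epithelium (-1.16, adjusted p = 4.20e-05). Their medians then ran from -0.50 to -0.28, -0.66 to -0.30, -1.45 to -0.42, -1.49 to -0.63 and -1.52 to -0.48. Without day 0 SE replicate 2 and day 7 HE replicate 1 together, ciliated cell markers (-0.16, adjusted p = 0.202) and mucins (-0.16, adjusted p = 0.374) were lost. The antimicrobial and acute phase list (-0.75, adjusted p = 0.00165) was lost without day 0 SE replicate 2 (-0.23, adjusted p = 0.131). Oestrogen-responsive genes (-0.61, adjusted p = 0.00597) and immediate-early genes (-0.61, adjusted p = 3.60e-07) were lost without day 7 HE replicate 1 (-0.06, adjusted p = 0.0899, and -0.02, adjusted p = 0.0705). Matrix remodelling (-0.24, adjusted p = 0.00121) and the IGF system (-0.31, adjusted p = 0.00121) were lost without day 7 HE replicate 2 (-0.38, adjusted p = 0.184, and -0.10, adjusted p = 0.413), with a larger median in the former and a smaller one in the latter. Over the single pools left out, medians ran from -0.57 to -0.28 for matrix remodelling, -0.70 to -0.10 for the IGF system and -1.24 to -0.02 for immediate-early genes. The remaining lists were each lost without any of several pools. With single pools left out, macrophage and dendritic cell markers (-0.55, adjusted p = 0.0166) ran from -1.03 to -0.14 and stromal fibroblast markers (-0.50, adjusted p = 0.00457) from -1.29 to 0.49. The unfolded protein response (-0.14, adjusted p = 0.00143) ran from -0.33 to -0.12 and oxidative phosphorylation (0.16, adjusted p = 0.00604) from 0.03 to 0.30.

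The lists higher in SE endometrium on day 0 could reflect inflammation, RNA quality, 1 pool, or the way the arrays happened to fall into groups. The EIF4E control, 3' minus 5', was higher in each SE pool (3.88 to 4.27) than in each HE pool (3.70 to 3.85). By this control, RNA quality and status cannot be told apart. The cyclophilin control, 3' minus 5', overlapped between HE (0.64 to 0.98) and SE (0.74 to 1.17). So did the GAPDH control (0.0560 to 0.141 in HE, 0.0264 to 0.578 in SE). The cell mix of the brush was not tested as a cause. Without SE replicate 2, which stood apart in its correlation with the others and its GAPDH control, 7 of the 15 lists kept their call. That pool alone may account for the antimicrobial, mucin and unfolded protein calls, which no other single removal ended. The IGF, complement, epithelial, interferon and lymphocyte calls were also lost without other pools. Not every such loss came with a smaller median: that of the complement system was 0.49 without HE replicate 2, against 0.31 with all pools. Fewer arrays alone can end a call, so these removals cannot show whether SE replicate 2 accounts for those lists. That pool alone does not account for the neutrophil call at the preset correlation, whose adjusted p was 3.57e-06 without it. With all pools the neutrophil list had an adjusted p = 0.295 with an estimated correlation. Status was set by polymorphonuclear cells on the brush, so the direction of the neutrophil list is not independent of the grouping. Over the 10 ways to split the 6 arrays, 1 gave as many lists as the real grouping (real value 15, highest other 13) and 3 gave as many probe sets (real value 3, highest other 7). The 10 splits are too few for a share under 0.05.

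The lower immediate-early genes in SE on day 7 might rest on 1 pool. Without HE replicate 1 the median was -0.0351, and without HE replicate 2 it was -1.10. Each removal left 1 HE pool, so these values show that the 2 HE pools differed, not which of them stood apart. Day 0 RNA in HE replicate 1 is a further candidate explanation. However, the 43 probe sets above 8 on day 0 and under 4 on day 7 in SE were low in that pool. Their median there lay 5.72 below their day 0 HE level (-5.72, interquartile range 2.51), close to that of HE replicate 2 (-5.89). Handling or sampling of HE replicate 1 could not be tested with the values used here.

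For the 3 lists lower in SE blastocysts, RNA input or amplification is a possible explanation, since the poly-A spikes lay 1.34 higher in HE than in SE (pooled SD 0.29) without overlap. The hybridisation controls, added after amplification, were higher in HE too (11.62 ± 0.19, n = 2, against 11.20 ± 0.19, n = 3; SD), and relative to them the spikes stood at 0.18 ± 0.12 and -0.74 ± 0.35, a smaller difference. With the spike level as a covariate all 3 calls ended, but the medians of oxidative phosphorylation (-0.15, from -0.13) and ribosomal proteins (-0.21, from -0.08) were no smaller, and only that of the unfolded protein response went to 0. Status and spike level moved together over the 5 arrays, so they cannot be told apart, and a biological difference in the embryos remains possible. A single pool was tested as well: over the 3 lists and 5 pools, 8 of 15 calls were lost, while every median stayed below 0 (-0.303 to -0.0364), so the test could not tell.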

How the results depend on the processing

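The number of arrays limits precision, and signals near the background limit what a log2 change can show. Of 355 gene results, 286 kept their direction and side of the threshold under every alternative, as did 201 of the 232 past it. Those 232 came from the comparisons between the days and from status on day 0. For status on day 0, 0 of the 3 calls were kept with the replicate number as a block. Of 43 gene lists, 0 kept their direction and side throughout. Over genes, 7462 of 7662 values were the same, 131 weaker, 27 stronger and 42 reversed; over lists 764 of 960, with 194 weaker and 2 reversed. Where a pool left out leaves 1 array in a group, that array is taken to vary like the other groups. Except where fewer units or members explain it, the cause was not tested.

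With no filter on low values the count of probe sets was 7 for status on day 0 and 10 on day 7, and 4 lists on day 7. With gene means, which test fewer units, the counts were 1 on day 0, 3321 between the days in HE and 3671 in SE, and 1 list in blastocysts; EED gave -0.0258 on day 0 and 0.0217 in the interaction, and LYZ2 1.79 between the days in SE. Median centring left 1 list in blastocysts. With only the compared groups in the fit, 0 probe sets passed on day 0, and 2 and 5 lists between the days in HE and SE. With all 16 arrays in 1 fit, blastocysts gave 473 probe sets and 0 lists. An estimated correlation left 0 lists in each of the 6 contrasts; fry left 0 for status on day 0, day 7, the interaction and blastocysts, and 10 and 11 between the days in HE and SE.

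The labels do not say whether replicate numbers pair the pools. Of same-numbered pairs, 2 of 15 in endometrium deviated together above 0.1 (-0.272 to 0.239), and 1 of 2 in blastocysts. By the pool numbers in the titles, 0 of 2 did (-0.0899 and 0.0339). Deviations from the means of so few arrays cannot exclude a pairing. With the replicate block, 0 probe sets passed for status on day 0, on day 7, in the interaction and in blastocysts, and 5408 and 6380 between the days in HE and SE. The lists called were then 15, 7, 15, 2, 1 and 3 in the same order, of which 15 of 15, 6 of 7, 13 of 14, 1 of 3, 1 of 1 and 3 of 3 were those reported; the others were newly called. The calls not kept were the complement system on day 7, oxidative phosphorylation in the interaction, and the unfolded protein response and ribosomal proteins in blastocysts. The correlation of status changes between the days was 0.192, PTGS2 -0.0603 in the interaction and GATA6 -0.0227. With the block by pool number, blastocysts gave 1 list and KRT18 -0.13.

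Of the alternatives chosen after seeing the data, leaving out day 0 SE replicate 2 and day 7 HE replicate 1 together gave 1 probe set and 8 lists for status on day 0, 11 lists on day 7, 1 list between the days in SE and 1 probe set in the interaction. Of the lists reported, 7 of 15 were kept on day 0, 4 of 7 on day 7, 1 of 3 between the days in SE and 9 of 14 in the interaction. PTGS2 was 0.0942 on day 0 and -0.98 in the interaction, G0S2 -0.00202 on day 7, and the correlation of endometrium and blastocysts -0.0550. The spike covariate gave blastocysts 0 lists, an unfolded protein response median of 0, IFNT2 1.45 and GATA6 -0.24.

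Leaving out each pool in turn, probe set counts ran from 0 to 11 for status on day 0, 0 to 2 on day 7, 4385 to 6434 between the days in HE, 5796 to 6634 in SE, 0 to 2 in the interaction and 0 to 0 in blastocysts. List counts ran from 8 to 16, 3 to 12, 1 to 2, 1 to 5, 11 to 18 and 1 to 3 in that order. Correlations ran from -2.76e-04 to 0.212 for status between the days, 0.917 to 0.952 for HE and SE between the days, and -0.0640 to 0.0323 for endometrium and blastocysts. For status on day 0, PTGS2 ran from -0.80 to 0.0942. On day 7, G0S2 ran from -0.00202 to 2.64, OXTR -1.05 to 0.21, PTGS2 -0.88 to 0.30, S100A12 -0.87 to 1.48, S100A8 -0.58 to 1.75 and S100A9 -0.24 to 1.53. Between the days in HE, CXCL8 ran from -3.48 to 0.25, IL1B -0.83 to 0.61, S100A8 -1.68 to 0.64 and S100A9 -1.61 to 0.64. In the interaction, CXCL8 ran from -1.46 to 2.27, OXTR -0.88 to 0.39, PTGS2 -0.47 to 0.71 and the stromal list -1.29 to 0.49. In blastocysts, GATA6 ran from -0.0227 to 0.0902, IFNT2 -1.04 to 0.14, KRT18 -0.13 to 0.41 and PAG2 -0.20 to 0.94.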

Other observations

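The hypothesis tested in this part and the splits were set before their results were seen; the genes named follow the same rule as in the report.

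Single members of further lists changed between day 0 and day 7 in both HE and SE, although none of these lists passed by camera; by fry heat shock and protein folding was lower in both (adjusted p = 0.00450 and 0.00573), and cholesterol and fatty acid synthesis in HE (adjusted p = 0.0207). Among stress genes, the heme oxygenase HMOX1 (2.72 in HE, 2.70 in SE) and the chaperone HSPA2 (2.38, 1.99) rose, while the small heat shock protein CRYAB (-3.65, -3.57), the collagen chaperone SERPINH1 (-2.45, -2.48), the secreted peroxidase GPX3 (-3.11, -3.59) and the growth arrest gene GADD45A (-3.52, -3.24) fell. In the cell cycle list thymidine kinase TK1 (1.60 in HE, 1.81 in SE) rose and the ribonucleotide reductase subunit RRM1 (-2.50, -2.04) fell. The glycolytic enzymes GPI (1.34, 1.58) and ALDOA (0.79, 0.92) rose, and the mevalonate enzyme PMVK (-2.88, -2.14) fell.

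Single members of immune and growth lists, none of which passed by camera either, changed in either direction. By fry the complement system was lower in SE (adjusted p = 0.0409) and the IGF system higher in HE (adjusted p = 0.0498). The chemokine CXCL16 (1.45 in HE, 1.79 in SE), the cytokine MIF (2.07, 1.77), the guanylate-binding protein GBP4 (2.56, 2.86), the interferon regulator IRF7 (1.36, 1.60), the peptide transporter TAP2 (1.10, 0.95), the leukocyte integrin ITGB2 (1.19, 1.13) and the oxidase subunit CYBB (1.45, 1.48) rose. The macrophage growth factor CSF1 (-2.84, -2.41), the lysosomal reductase IFI30 (-3.12, -3.97), the dendritic cell marker CD83 (-3.28, -2.87), IFI35 (-1.12, -0.84) and CLU (-1.19, -1.50) fell. Of growth regulators, CCN2 (1.40, 1.54) rose and IGFBP4 (-2.23, -3.04) fell.

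A status difference shared by both days was tested as a hypothesis on the mean SE over HE change. limma gave no call for it: 0 probe sets passed, with 805 at an unadjusted p under 0.05 against 671 expected by chance. The smallest adjusted p was 0.0519, for PSTPIP2 (0.89), and LYZ2 stood at 1.17 (adjusted p = 0.110).

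Of the 10 splits of the 6 SE arrays, 1 gave as many probe sets between the days as the real grouping (real value 6723, highest other 0) and 9 gave as many lists (real value 3, highest other 14); 10 splits are too few for a share under 0.05.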
